A study of Drosophila melanogaster with 2 samples.

How the data were processed

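The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) from whole fruit flies, Drosophila melanogaster, of mixed sex at the white prepupa stage, the start of metamorphosis. Per the labels, the flies carried a transgene that expresses espinas (esn) with green fluorescent protein (GFP) at its C-terminus, chromatin was fragmented by sonication, and the precipitation used an antibody against GFP. The 2 samples are biological replicates 1 and 2 of this single group, so no comparison between groups was possible. The labels do not say how the replicates' animals were raised or collected, so the spread between the replicates may be partly technical.

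The deposited files were peak lists in narrowPeak format on the genome builds dm6 and dm3. Per the deposited file descriptions, the authors made 1 list from each replicate and 1 list from both replicates pooled, each against a control file, and derived an IDR list (regions kept after an irreproducible discovery rate threshold) from them. The caller, its version and the threshold are not given in the sources used here. The control libraries were not analysed here. Each region carries the authors' signal value, a measure of enrichment whose scale is not stated and differs between lists, so it was used only to describe, rank or filter regions within a list. The summit is the authors' position of highest signal, deposited as an offset in bases from the start of the region. In the IDR list on dm6, 5 summits lay at the end coordinate of their region, 1 base beyond it, and were kept. The files give no read counts, so the depth of each library is unknown and no value here carries a depth-based error. Intervals on shares are 95% Wilson intervals unless said otherwise and cover counting error only.

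Coordinates are 1-based on dm6. Genes and transcripts came from Ensembl release 115 (BDGP6.54) and sequence from Release 6 of the genome, which has the dm6 coordinates. The chromosome arms 2L, 2R, 3L, 3R, 4 and X were used, which left 10918 of the 10936 IDR regions. No coordinates were converted between builds. Calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

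The tests, their settings, the gene lists, the motifs and the rule for naming genes were fixed before the data were examined, except where stated otherwise. Replicates were compared over the strongest 10918 regions of each list, a region being shared when it overlapped by 1 base or more, against 1000 circular shifts of the regions within each arm (one-sided permutation test). A promoter summit is one within 500 bases of the start of a protein-coding transcript. A summit in more than 1 annotation class was counted in the first of promoter, 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic. Promoter shares and annotation classes were tested with the same kind of shift, one-sided and two-sided respectively, and the smallest one-sided p these can give is 0.001. Density per arm was tested with an exact binomial test. For 22 gene lists, the share of members with a promoter summit was compared with all other protein-coding genes by Fisher's exact test, two-sided. For 26 short sequence motifs, presence within 100 bases of the summit was compared with a flank window centred 1000 bases from the same summit by an exact McNemar test, two-sided, and G+C content by a sign-flip permutation test with 100000 resamples, two-sided, for which the smallest p is 1e-05. Adjusted p-values are Benjamini-Hochberg values over the lists, motifs, arms or classes of that family. Genes and regions are not replicates, and these p-values describe this pair of libraries.

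The genes named are esn and the planar cell polarity list, the genes with a start within 500 bases of the 10 strongest IDR regions found in both replicate lists, the members of each list with the strongest promoter region (up to 3 per list), and the strongest 5 regions away from promoters. Genes named outside this rule were chosen after their values were seen, which holds for the additional families and short sequences of the closing observations. The list words d and Dl did not match the annotation and were matched to its symbols dachs and Delta after the first list results had been seen. Without them the planar cell polarity and Hippo lists each held 11 of 18 members with a promoter summit, exact adjusted p = 0.049973.

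Alternatives fixed beforehand replaced the IDR list with the strongest 10918 regions of either replicate or with its own strongest 5459 regions, changed distances, windows, overlap rules and backgrounds, and used dm3. Alternatives added after seeing the data were local shifts of 5 to 20 kilobases, single summits per run of overlapping regions, stratification of the gene lists by number of transcript starts (pooled Mantel-Haenszel odds ratio with an exact conditional p, which replaced an asymptotic p after its values had been seen), dinucleotide-shuffled windows, leaving out genes within 100 kilobases of esn, and leaving out the renamed members. The procedures were tested on simulated data. With lists of the real sizes among 13945 genes, 2.73% of 440 unchanged lists were called, and 93.6% of 440 lists with a member share of 80% were called. Smaller rises and lowered shares were not simulated, so power for these is unknown. Members were drawn at random and each gene received a summit independently. Neighbours that share a promoter summit and gene families clustered in the genome were therefore not simulated, and the rate of calls for such lists is unknown. The overlap test called 1 of 10 pairs of independent lists. The promoter test called 0 of 20 sets of uniform summits, and the motif test 1 of 260 comparisons in random sequence.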

Results

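Regions enriched by precipitation of GFP-tagged espinas were mapped in white prepupae. Below, bound means that the lists held a region or summit there. The series has no untagged group and the control libraries were not analysed. Binding by espinas therefore cannot be told apart from recovery unrelated to it. Espinas is a LIM-domain protein related to Prickle (pk), a core component of planar cell polarity, the orientation of cells within the plane of an epithelium. The group had 2 biological replicates. The IDR list held 10936 regions on dm6 with a median width of 476 bases, which covered 4.04 Mb, or 3.02% of the arms. Exactly this width was held by 48.6% of them, so the median may not measure the extent of enrichment. Of the regions, 237 repeated the coordinates of an earlier one, and the 10918 on the arms formed 9810 runs of overlapping regions. The counts below are of regions, not of separate places. The pooled list and both replicate lists held 30000 regions each. On dm3 the IDR list held 10901 regions. The IDR list was exactly the strongest 10936 regions of the pooled list by signal value. The signal values below are the authors' and have no stated scale, and depth is unknown.

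The first question was whether the replicates bound the same places. The strongest region of the IDR list, in an intron of ush (u-shaped, a GATA factor cofactor), ranked 1 in both replicates, and the region at CG14100 ranked 2 in both. Of the strongest 10918 regions of replicate 1, 9104 (83.4%) overlapped one of replicate 2, against a mean of 5.77% for shifted regions (one-sided permutation p = 0.001, the smallest possible). In the reverse direction 9553 (87.5%) overlapped, against 6.01% (permutation p = 0.001). The IDR regions are the strongest of the pooled list, which was made from both replicates, so their values in the replicate lists describe that list and are not a separate test. Of those on the arms, 10767 (98.6%) overlapped a region in both replicate lists, and 9200 (84.3%, interval 83.6 to 84.9) overlapped one of the strongest 10918 regions of both. That last share was 99.6% in the strongest 2184 IDR regions and 42.5% in the weakest 2183. Across 10767 regions, which are not independent, Spearman's rho between the replicates' signal values was 0.828. Within 5 groups cut by pooled signal, rho was 0.756 in the strongest and 0.152, -0.0685, -0.116 and -0.0666 in the following ones, whose ranges of pooled signal were narrow (164 to 208 in the weakest). The pooled signal is made from both replicates, so cutting by it lowers rho within a group by construction, and these values do not measure how far the replicates differ.

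Of the 10 strongest IDR regions, 5 lay at promoters and 5 elsewhere. The promoter regions lay at CG14100 (3L, 19590351 to 19590881, signal 8139), CG1888 (2R, 9546880 to 9547718, signal 7366), Ugalt, a UDP-galactose transporter (X, 2703627 to 2704180, signal 7190), PNPase, a mitochondrial RNA-processing enzyme (3R, 31404414 to 31404953, signal 6907), and the pair CenG1A and mRpS23 (2L, 13835195 to 13835721, signal 6279). Of the regions away from promoters, the strongest lay in an intron of ush (2L, 480502 to 481427, signal 8950), 1380 bases from the nearest coding start, that of cbt. Others lay in introns of CG11050 (2L, 6612382 to 6612985, signal 7188) and of Lk6, a protein kinase (3R, 11760744 to 11761413, signal 6881). An intergenic region lay 11918 bases from CG13323 (2R, 13035015 to 13035613, signal 6870). The last lay in an exon of lncRNA:CR46035 within the span of osa, a chromatin remodelling subunit (3R, 17704087 to 17704701, signal 6241).

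Summits were concentrated at promoters and nearly absent from coding exons. Of 10918 summits, 4577 (41.9%, interval 41.0 to 42.8) were promoter summits, 3.67 times the mean of 11.4% for shifted summits (one-sided permutation p = 0.001). The share was 40.9% with the regions of replicate 1 alone and 42.8% with those of replicate 2 alone. Only 24 summits (0.220%) lay in coding exons outside promoters and 5′ UTRs, against 13.9% for shifted summits, and 91 (0.833%) lay in 3′ UTRs against 4.53% (both permutation adjusted p = 0.0035). Introns held 4129 summits (37.8% against 39.9%, permutation adjusted p = 0.0397) and intergenic sequence 1830 (16.8% against 27.9%, adjusted p = 0.0035). For 5′ UTRs the values were 0.586% against 0.790% (permutation adjusted p = 0.0397), and for other exons 1.86% against 1.60% (adjusted p = 0.0859). Without replicate 2 the permutation adjusted p was 0.186 for both introns and 5′ UTRs, and for introns it was 0.244 in the strongest 5459 regions. A larger promoter share lowers the others by construction. Counted only among summits outside promoters, introns held 65.1% against 45.0% for shifted summits, 5′ UTRs 1.01% against 0.892%, intergenic sequence 28.9% against 31.5%, other exons 3.20% against 1.80%, coding exons 0.378% against 15.7% and 3′ UTRs 1.44% against 5.11%, differences that were not tested. No trend of the promoter share with signal passed the test (Spearman's rho across regions -0.0012, permutation p = 0.901).

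**Figure D1:**
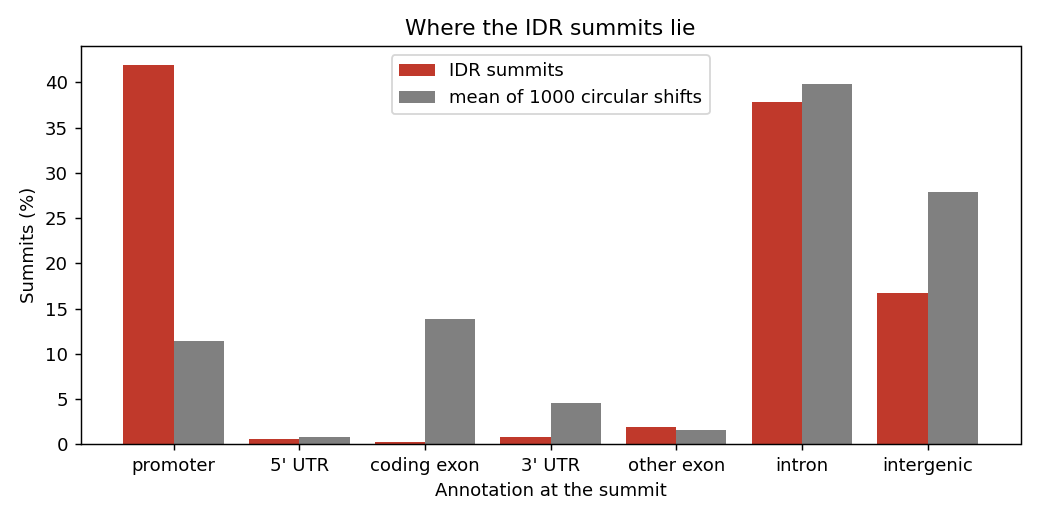
Percent of the 10918 IDR summits (red bars) and mean percent over 1000 circular shifts (grey bars) in each annotation class, a summit near a coding start counting as promoter first. Promoters hold 41.9% of summits against 11.4%, and coding exons 0.220% against 13.9%.

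Chromosome 4, the smallest, was sparsely bound. It held 42 regions, 31.2 per Mb (exact interval 22.5 to 42.1), against 81.6 per Mb over all arms (exact binomial test, adjusted p = 1.24e-12). The X held 87.0 per Mb (exact adjusted p = 0.00422), 3L 85.8 (adjusted p = 0.00721) and 2R 77.0 (adjusted p = 0.00721). For 2L and 3R the values were 82.4 and 78.9 per Mb (exact adjusted p = 0.624 and 0.0680). Without replicate 1 the X was at 83.9 per Mb (exact adjusted p = 0.191) and 3R passed the threshold at 78.0 (adjusted p = 0.0226). In the strongest 5459 regions, only 4 (10 regions) and 3L kept an exact adjusted p under the threshold.

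The gene of the tagged protein also held summits. The flies carried an esn transgene, depth is unknown and the control libraries were not analysed. Added copies of esn sequence therefore cannot be told apart from binding at this gene. The extent of the added sequence was not examined, so the same limit may hold for genes close to esn. Within esn (FBgn0263934, 2R, 7086316 to 7127868, plus strand) lay 9 IDR summits. The strongest, in an intron at 7094357, had a signal of 2120 and ranked 252 in the IDR list, 265 in replicate 1 and 260 in replicate 2. The next, in an intron at 7093067, had a signal of 828. The strongest esn promoter summit, at 7086226 and 90 bases from the start of the gene, had a signal of 272. Of the 9 summits, the one at 7106572 (signal 171) was also a promoter summit, 108 bases from the start of a shorter esn transcript.

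**Figure D2:**
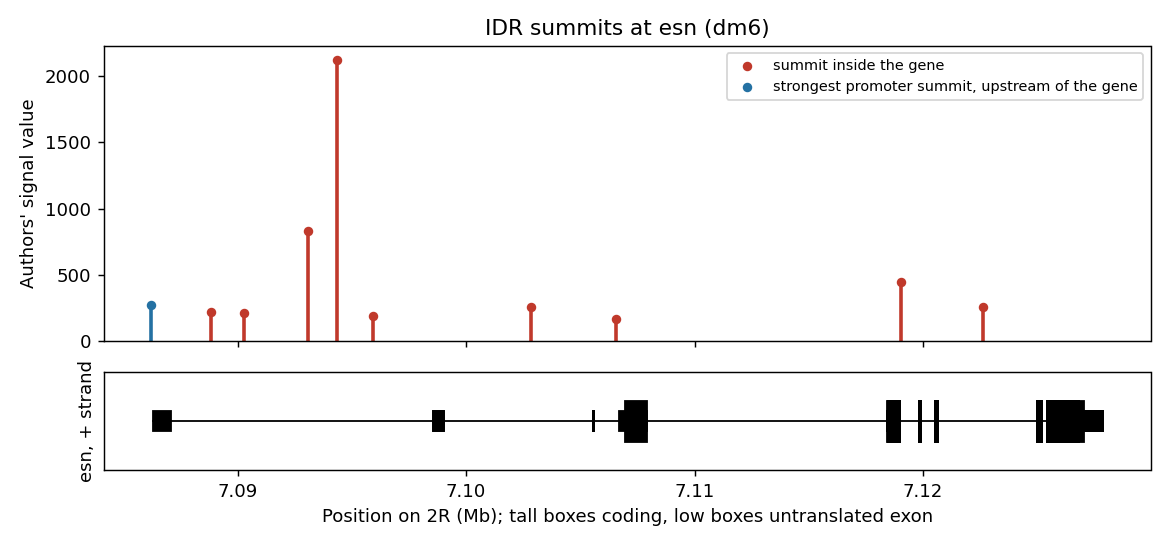
Authors' signal value (vertical axis) of each IDR summit at esn by position on 2R in Mb, with the exons of esn below. The 9 summits inside the gene are red, among them a promoter summit at 7106572, and the strongest promoter summit, at 7086226 upstream of the gene, is blue. The highest stands at 2120.

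Of the 6 core planar cell polarity genes, 4 had a promoter summit. These were pk (247), Vang, which encodes a transmembrane protein that binds Prickle (233), dgo (223, shared with Prosbeta5) and stan, which encodes an atypical cadherin (190). All 4 signals lay below the median of the IDR list, 328. The genes fz, the receptor Frizzled, and dsh, its cytoplasmic partner Dishevelled, had no promoter summit in the IDR list. Among the strongest 10918 regions of each replicate, pk and Vang had a promoter summit in both, dgo and stan in replicate 1 alone, and fz in replicate 2 alone. The gene body of fz held 19 IDR summits and that of dsh 0. Stronger promoter summits lay at app (1022), ft (769, in the strongest 10918 regions of replicate 2 alone), the pair Rok and RpS19a (652), the pair Rho1 and CG8414 (378) and the pair fy and emb (372). The others were esn itself, described above, dachs (233) and the pair nmo and Pop4 (171), and ds, fj, frtz, in and mwh had none. Over the list, with esn itself counted, 12 of 19 members (63.2%, interval 41.0 to 80.9) had a promoter summit against 35.4% of all protein-coding genes (Fisher's exact test, adjusted p = 0.0296). The odds ratio was 3.13. It was 2.85 when stratified by number of transcript starts (exact adjusted p = 0.0777) and 2.55 without replicate 2 (0.103). At 250 bases it was 2.12 (exact adjusted p = 0.196), and in the strongest 5459 regions 1.41 (0.654). Without genes within 100 kilobases of esn it was 2.61 (exact adjusted p = 0.131). That setting leaves out the tagged gene itself and a further member with a promoter summit, so it does not isolate the effect of esn.

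The highest shares were those of the cytosolic ribosomal protein, ecdysone response and axon and dendrite lists. Cytosolic ribosomal protein genes had promoter summits in 74 of 88 members (84.1%, exact adjusted p = 5.47e-20). The strongest were at RpS27 with Nup37 (2090), RpL7 with Ripalpha (2040) and RpL32 with CG7943 (1860). Of the genes of the response to ecdysone, the steroid that triggers metamorphosis, 26 of 35 had one (74.3%, interval 57.9 to 85.8, exact adjusted p = 1.45e-05). They were led by Sox14, an ecdysone-induced transcription factor (4314), E23, an ABC transporter (2932), and Ldh, lactate dehydrogenase (2603). Axon and dendrite genes had 18 of 27 (exact adjusted p = 0.00303), with tutl (1803), trio (552) and Ten-a (458). Chromatin and insulator genes had 20 of 31 (exact adjusted p = 0.00303), led by Chro with Ssl1 (6215), Cp190 with CG4338 (2304) and brm with Arl1 (1684). Neighbours that share a promoter summit are not told apart, and 4936 of 13945 genes had a promoter summit by this count.

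Cell cycle genes had 18 of 28 (exact adjusted p = 0.00574), with Dp (1244), RnrS with CG34231 (916) and Mcm2 with RPA1 (821). Hippo pathway genes, which control organ growth, had 12 of 19 (exact adjusted p = 0.0296), with app, Mer (945) and ft, and share members with the polarity list. Proteasome genes had 23 of 43 (exact adjusted p = 0.0296), with Rpn5 and Hat1 (1195), Rpn3 and l(2)37Bb (1096) and Rpt5 and RanBP3 (610). In the strongest 5459 regions the exact adjusted p was 0.0522 for the ecdysone list, 0.175 for axon and dendrite, 0.137 for cell cycle, 0.169 for Hippo and 0.891 for proteasome genes. The proteasome call was also lost with either replicate alone (0.164 and 0.130), at 1000 bases (0.124), by gene body (0.133) and for genes with no close neighbour (1), the cell cycle call without replicate 2 (0.103) and the Hippo call without replicate 1 (0.0935). Stratified by number of transcript starts, the exact adjusted p was 0.0649 for both the Hippo list (odds ratio 2.45, from 3.13) and the axon and dendrite list (2.39, from 3.66). At 250 bases it was 0.406 for the Hippo list. For the ecdysone list the odds ratio of 5.30 fell to 3.26 when stratified (exact adjusted p = 0.0149) and to 2.50 at 250 bases (0.0207). It rose to 9.16 by gene body (exact adjusted p = 2.00e-07) and to 10.1 among genes with no close neighbour (2.78e-08).

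Cuticle protein, chemoreceptor, testis and accessory gland, and salivary glue genes were rarely bound. Cuticle protein genes had promoter summits in 4 of 121 members (3.31%, exact adjusted p = 6.59e-17), with Cpr73D with Ogdh (266), Cpr49Ah (262) and Cpr12A (239). Chemoreceptor genes had 4 of 180 (2.22%, exact adjusted p = 4.34e-27), with Ir60e and CG13585 (493), Gr63a and Lamtor4 (309) and Ir94f (301). Testis and accessory gland genes had 2 of 69 (2.90%, exact adjusted p = 3.79e-10), Sfp26Ad with Gpdh1 (721) and Mst85C with Nmdmc and Rel (369). None of the 23 salivary glue and late puff genes had one (0%, upper bound 14.3%, exact adjusted p = 0.000278). Restricted to genes with no other start within 500 bases, still no member had one (odds ratio 0), and the exact adjusted p was 0.214.

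The other 10 lists did not pass the test. LIM-domain genes had 13 of 23 (exact adjusted p = 0.0801), with Pax, Alp12 and CG13085 (1849), Lmpt (969) and Mical with CG3909 (684). Heat shock genes had 10 of 20, of which Hsp27 (5494), Hsp83 (1894) and Hsp26 (1835) had strong regions. Fat body genes had 8 of 19, with Lpin (4351), Hnf4 (1490) and FASN1 (690). Notch pathway genes had 9 of 22, with E(spl)m3-HLH (1813), numb (1595) and E(spl)m7-HLH (1538). Imaginal disc patterning genes had 11 of 31, with so (518), bi (261) and Dll (235). Hox and Polycomb-related genes had 9 of 30, with ph-p (3627), ph-d (535) and Su(z)2 (278). Glial genes had 4 of 12, with moody (1305), Gli (1258) and wrapper (191). Neuronal genes had 4 of 19, with elav (2464), Csp (274) and Syx1A (271). Muscle structure genes had 5 of 26, with Msp300 (2994), Tm1 (886) and Mef2 (279), and hemocyte genes 2 of 15, at ush (414) and crq (224). The LIM-domain list passed the threshold without replicate 1 (0.0285), by gene body (0.0294) and among genes with no close neighbour (0.0199). Its odds ratio of 2.38 was 1.07 when stratified by number of transcript starts (exact adjusted p = 1) and 1.10 in the strongest 5459 regions (0.877), and without genes within 100 kilobases of esn the adjusted p was 0.166. Disc patterning genes had more summits when the gene body was counted (0.0104) and fewer in the strongest 5459 regions (0.0402). Stratified by number of transcript starts, neuronal, muscle and hemocyte genes had fewer summits than other genes (exact adjusted p = 0.0149, 0.00201 and 0.0427).

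**Figure D3:**
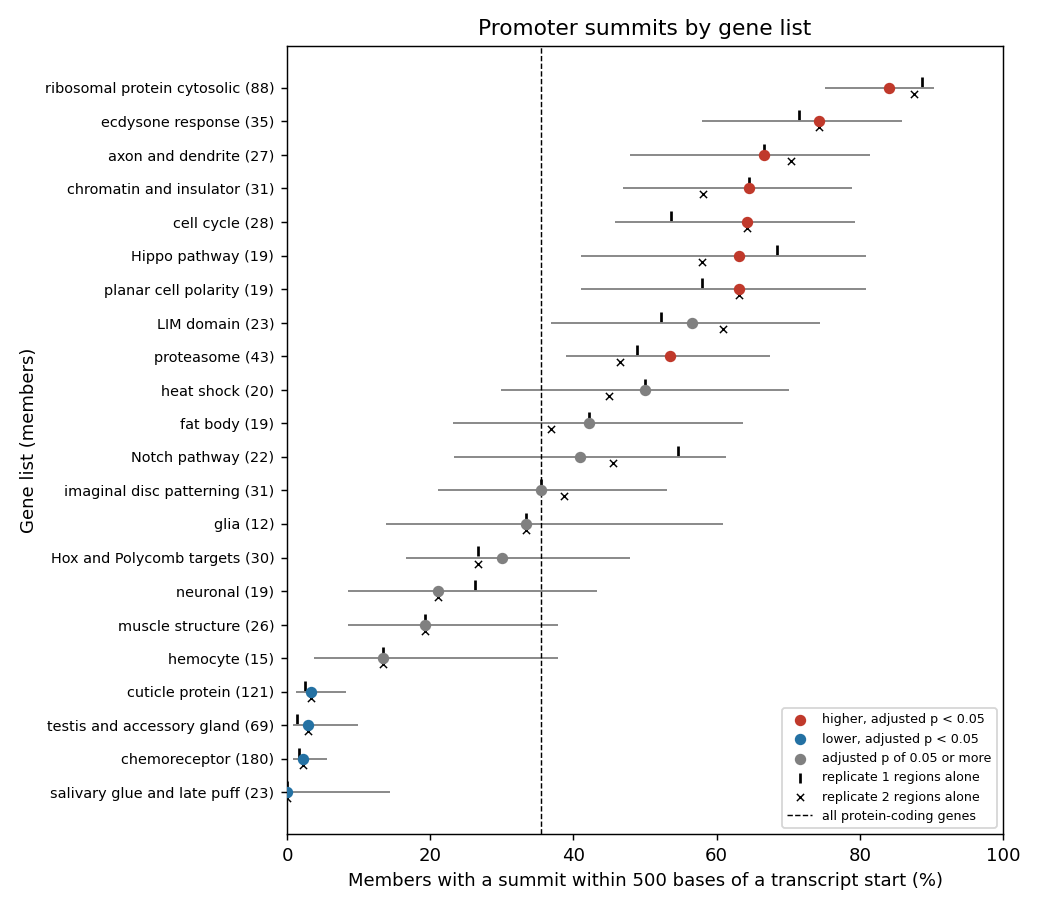
Percent of the members of each of the 22 gene lists with a promoter summit (points, with 95% Wilson intervals), red or blue where the adjusted p is under 0.05, with the values from each replicate's own strongest regions as ticks and crosses and all protein-coding genes as a dashed line at 35.4%. Cytosolic ribosomal protein genes stand highest at 84.1%.

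Sequence at the summits was AT-rich, and several core promoter sequences, though not the initiator, were more frequent there than in flanks. Mean G+C content within 100 bases of the summit was 35.8% ± 7.45 (SD over 10918 regions) against 42.5% ± 9.49 in the flank windows, a difference of -6.65 points (sign-flip permutation p = 1e-05, the smallest possible). It was -6.64 in the regions of replicate 2 alone and -6.42 in those of replicate 1 alone. The DNA replication-related element TATCGATA, bound by Dref and BEAF-32, was present in 3.80% of summit windows and 0.522% of flanks (exact adjusted p = 1.98e-67). The core promoter sequence GGTCACAC, named Motif 1, was present in 2.58% and 0.531% (exact adjusted p = 3.77e-36). Ohler motif 6 was present in 4.48% and 1.90%, and Ohler motif 7 in 5.92% and 2.98% (exact adjusted p = 3.96e-27 and 2.15e-26). The initiator was present in 17.9% and 17.3% (exact adjusted p = 0.252). It passed the threshold at promoter summits alone (ratio 1.13, exact adjusted p = 0.0104), within 50 bases (1.10, 0.0490) and against shuffled windows (1.09, 0.00523). Against windows at the same distance from starts without a summit, the ratio for TATCGATA was 2.43 in place of 7.28 and that for Motif 1 was 1.76 in place of 4.86 (exact adjusted p = 2.48e-25 and 5.46e-09), and the initiator was less frequent at summits (ratio 0.879, adjusted p = 6.37e-06). The sequence TATAAA was present in 35.6% of summit windows and 22.1% of flanks (exact adjusted p = 3.26e-105). Dinucleotide-shuffled summit windows held it in 31.7%, promoter summits in 33.5% and summits away from promoters in 37.0%.

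Of the 26 motifs, 11 were more frequent and 8 less frequent at summits than in flanks. The GC-rich Mad sequence was present in 6.14% of summits and 12.3% of flanks (exact adjusted p = 3.60e-55), and the ftz-f1 site in 0.696% and 1.89% (adjusted p = 1.47e-14). At summits away from promoters, the exact adjusted p was 0.839 for TATCGATA, 0.892 for Motif 1 and 0.342 for Ohler motif 7. Against dinucleotide-shuffled windows, 4 sequences that were less frequent than in flanks were more frequent at summits. Their ratios to the shuffled share were 1.31 for Mad, 1.71 for Su(H), 2.30 for the CTCF core and 6.68 for the CA repeat (exact adjusted p = 1.49e-06, 1.58e-06, 1.27e-07 and 7.28e-69), against 0.501, 0.786, 0.672 and 0.797 to flanks. The GATA and homeodomain sequences turned the other way, from 1.21 and 1.45 to 0.911 and 0.933 (exact adjusted p = 7.72e-06 and 0.0211). At the same distance from starts without a summit, the CTCF core was also more frequent, at 1.39 times (exact adjusted p = 0.0294).

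**Figure D4:**
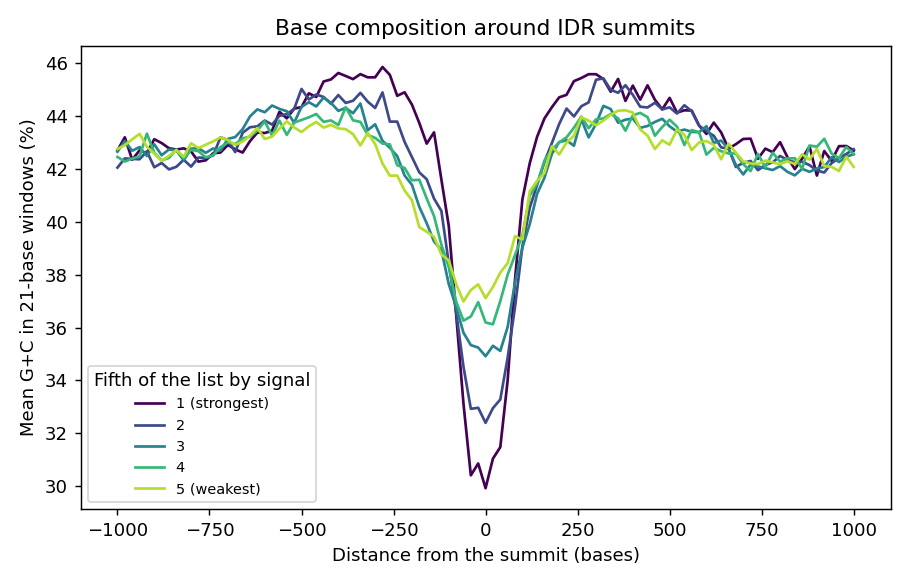
Mean G+C content in 21-base windows (vertical axis, percent) by distance from the summit (horizontal axis, bases), with the IDR list ranked by signal and divided into 5 groups, 1 line each. Within 100 bases of the summit the mean is 33.6% in the strongest 2184 regions and 37.9% in the weakest 2183.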

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

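A signal outside the chromosome arms used in the comparisons drew attention. On dm6, 18 IDR regions lay on the mitochondrial genome and covered 5559 bases of it, with a best rank of 309. The list of replicate 2 held 22 such regions, its best at rank 34, and the list of replicate 1 held 0. On dm3 the list of replicate 2 held 6 and the IDR list held 0. On dm3, 8 IDR regions lay on sequences other than the arms and the mitochondrial genome. No explanation was tested for these regions.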

How the results depend on the processing

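Depth is unknown, so its limit on these results cannot be given. No paired analysis was possible because the series has a single group. The pooled list at the length of the IDR list is the IDR list itself, so that alternative tests nothing. Of 75 values of the main results under the other alternatives, 61 kept their direction and their side of the threshold or stayed within 1.5 times the main count. The promoter excess, replicate overlap and G+C difference did so under every alternative run. For the first 2 only the side of the threshold could change, since a share has no opposite direction. With local shifts of 5 to 20 kilobases the shifted promoter share was 15.0%, and the ratio was 2.79 in place of 3.67. In the strongest regions of the IDR list, which by construction hold fewer, there were 5468 regions, 2 arms and 2 higher gene lists passed the threshold, and the promoter trend was 0.0248 (permutation p = 0.0668). Without a replicate, the higher gene lists numbered 5 to 7 and the promoter trend ranged from -0.0091 to 0.0165 (permutation p = 0.344 and 0.0855). Stratified by number of transcript starts, 5 lists were higher and 7 lower, an alternative chosen after seeing the data. The rank correlation was 0.853 with close summits, and the build ratio of sorted signal was 1.03 in the pooled and 1.01 in the IDR list. Away from promoters 5 motifs were more frequent. At promoters only, at the same distance from unbound starts and against shuffled windows (also added later), 5 were less frequent in each case. Ratios of motifs turned against shuffled windows for Mad (1.31), Su(H) (1.71), the CTCF core (2.30), the CA repeat (6.68), GATA (0.911), the homeodomain (0.933), CAGCTG (2.75) and the heat shock element (0.959). At the same distance from unbound starts they turned for the CTCF core (1.39), CA repeat (1.15), initiator (0.879) and heat shock element (0.982). At promoters only they turned for CAGCTG (1.18), CA repeat (1.14), grainyhead (1.33) and pho (1.19), away from promoters for GAGA (0.899), the initiator (0.975), TEAD (1.09) and Creb (0.737), in the strongest regions for GAGA (0.889), the initiator (0.958) and pho (1.01), and within 50 bases for pho (1.11). Without a replicate they ranged from 0.788 to 1.05 for grainyhead and from 0.875 to 1.06 for Creb. Odds ratios of lists without a call turned for fat body (0.854 stratified), disc patterning (0.131 in the strongest regions, 0.704 stratified), Hox and Polycomb (1.16 by gene body, 1.21 for genes without a close neighbour), Notch (0.693 at 250 bases), neuronal (1.06 without a close neighbour) and glia (1.53 at 1000 bases, 1.52 by gene body, 1.37 without a close neighbour). The cause was not tested.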

Other observations

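The tests in this part were chosen after the data had been seen, except the G+C difference at summits away from coding starts, which was planned as an alternative and whose reading as a test of promoter composition was set afterwards. Among 12 further gene families, tested together, mitochondrial ribosomal protein genes had promoter summits in 51 of 73 members (69.9%, interval 58.6 to 79.2, Fisher's exact test, adjusted p = 4.11e-08). They were led by mRpS23 with CenG1A, mRpL41, and mRpS10 with Art3. These families were not retested among genes with no close neighbour or by number of transcript starts. Translation factor genes had 26 of 52 and vacuolar ATPase genes 18 of 33 (both exact adjusted p = 0.0448). Cytochrome P450 genes had 9 of 85 (exact adjusted p = 1.09e-06), odorant-binding protein genes 2 of 51 (9.13e-07), and lectin and antimicrobial peptide genes 2 of 31 (0.00063). Jonah protease and trypsin genes had 0 of 27 (4.73e-05) and the yellow family 0 of 13 (0.0123). Respiratory chain genes had 36 of 84 (exact adjusted p = 0.185), glutathione S-transferase genes 11 of 35 (0.725) and nuclear receptor genes 12 of 21 (0.0559). Rab genes, with Rab3GAP1 counted among them, had 16 of 31 (exact adjusted p = 0.075). None of these families passed the threshold.

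TATCGATA and Motif 1 were scarcer in the strongest summits. TATCGATA was present in 1.74% of the strongest 2184 and 3.99% of the weakest 2183, with its highest share, 5.49%, in the next-weakest group, and Motif 1 in 0.916% and 3.48%. TATAAA ran the other way, with 39.9% and 30.8%. Mean G+C content at the summits was 33.6% and 37.9% in these groups, and 33.8% and 40.1% at their promoter summits. The motif trends were not adjusted for it, so those of TATAAA and of Motif 1 (GGTCACAC) cannot be told apart from base composition. No trend over all summits passed the test for Ohler motif 6 (4.49% and 4.58%) or Ohler motif 7 (4.85% and 6.23%, permutation adjusted p = 0.716 and 0.0968). Among promoter summits, Spearman's rho with signal was -0.0739 for TATCGATA, -0.106 for Motif 1 and 0.119 for TATAAA (permutation, each p = 0.0001, the smallest possible). For Ohler motif 6 it was -0.0473 there (permutation adjusted p = 0.0039). With its 9 summits, esn stood at percentile 91.0 of the 433 coding genes of 30 to 60 kb, of which 29 had more. In the lists of replicates 1 and 2 it stood at percentiles 83.1 and 91.2, with 62 and 35 genes having more. Among 8-base sequences of the strongest summits on 2L, 2R and 3L, CACAGTGG ranked first by excess over shuffled windows, scaled to their count. More of those summits held CACTGAGA (66) and TCAGTGCA (60) than CACAGTGG (49). On 3R, X and 4, CACAGTGG was present in 5.26% of 893 such summits, against 1.34% of flanks and 0.112% of shuffled windows (exact McNemar, adjusted p = 3.31e-06 and 7.83e-13). There CACTGAGA was present in 3.02% against 0.224% of flanks, and TCAGTGCA in 4.03% against 0.448%. Short sequences had been looked at on all arms before, and repeats were not examined.

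Of the technical explanations of the AT-rich summits, the composition of promoters alone is argued against. Summits over 500 bases from every coding start were also lower in G+C than their flanks, by a difference of -6.33 points (SE 0.133). Coding sequence in the flanks was not separated. It made up 22.4% of random positions within 5 kb of a summit, 7.49% when matched to the summits on G+C content, and held 0.714% of summits. Differences to flanks, of G+C and of motifs, may therefore partly reflect it. Preferential recovery of AT-rich DNA stays open, as no test here bears on it and the control libraries were not analysed. No biological explanation was tested.

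The scarcity of summits in coding exons was larger than base composition gave. Counting promoters too, 78 of 10918 summits (0.714%, interval 0.573 to 0.891) lay in coding sequence, against 22.4% of random positions within 5 kb of a summit and 7.49% of such positions matched on G+C content, so composition may account for part but not all of it. The excess of summits at promoters is argued against as the cause, since 0.394% of summits over 500 bases from every coding start lay in coding sequence, those also annotated as 5′ UTR included. No biological explanation was tested, as the design has no second group.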
